A study of Homo sapiens with 9 samples.

How the data were processed

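Bulk RNA sequencing of human cells was available as 1 table of 9 libraries, 3 labelled si-NC, 3 labelled si1-BCLIN25 and 3 labelled si2-BCLIN25. Groups and replicate numbers were taken from the library titles, which name the paclitaxel-resistant breast cancer line MDA-MB-231/PTX. Other label fields of the same libraries name the gefitinib-resistant lung adenocarcinoma line PC9/GR and knockdown of another RNA, HUMT. The labels therefore do not settle which cells were sequenced or which RNA was targeted. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made for the BGI500 sequencer. In the header of the deposited table the control columns carry a prefix that the siRNA columns lack and that no label explains, so the controls could have been handled in a separate batch, and group and batch cannot be told apart.

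The deposited values are FPKM, fragments scaled to transcript length and to the total of mapped fragments, per the file headers. Per the submitters' processing notes, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 were used, with no role or order stated. The genome build and the annotation are not given in the sources used here. FPKM corrects for transcript length and for the total of mapped fragments, and a few very abundant genes can still shift the values of all others in a library. FPKM summed to between 394081 and 419025 per library, and the 10 most abundant genes held 4.65% to 5.60% of that sum. Sequencing depth is unknown. Among 187 low genes, only 49.9% of values were whole multiples of the gene's smallest step within a tolerance of 0.1, so reads could not be recovered, and no counting interval or detection floor is given.

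The table analysed held 18064 rows under numeric gene identifiers, of which 17748 matched a symbol in NCBI's RefSeq gene table for GRCh38.p14. That table was used for names and for the order of neighbouring genes, and no coordinates are printed since the authors' build is unknown. Of the rows tested, 10 held the same 9 values as another row, as happens where near-identical genes share reads. BCLIN25, HUMT and CRP were not analysed here, nor were mitochondrially encoded genes.

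Values were transformed to log2(FPKM + 1), and fold changes are on that scale, which understates changes of low genes. Genes with at least 1 FPKM in at least 3 libraries were kept, 12317 in all. A model of group means over all 9 libraries was fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend), so that the 3 groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05 and no fold minimum. A gene past the threshold is described as called, and as having risen or fallen. Every adjusted p given for a gene is from this model. The fold minimum of 2 used for some counts is an absolute log2 fold change of at least 1. Gene lists of at least 5 tested members were compared with the other genes by camera in limma, with an inter-gene correlation preset at 0.01, adjusted over the 31 lists tested. Camera was run again with an estimated correlation and beside fry, whose p tests whether the genes of a list move, on balance, in one direction.

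The groups, lists, tests and the rule for named genes were fixed before the data were examined. Per comparison with si-NC the rule took the 10 largest rises and falls among called genes whose libraries did not overlap between the groups and whose mean level reached the median of the genes tested. It took 12 each way for both siRNA groups together, 5 each way between the siRNA groups, up to 4 members per list with the smallest p, and the genes in the design text. Markers of cell lines and cell types came from lists fixed in advance, but which of them are named was chosen after their values were seen. Other genes named outside the rule are marked as such.

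The model was tested on simulated data made from the means and spreads of these libraries, for si1-BCLIN25 against si-NC over 12317 genes. In the simulated data 200 genes above a minimum level were changed, with the normal spread that the model assumes. The model recovered 74% of changed genes at a fold of 1.25, 94% at 1.5 and 100% at 2 and 4. It called 11 unchanged genes, and 0 genes in a simulated unchanged group. Far more genes were called in the real libraries, so these rates may differ there. Since both siRNA groups were compared with the same controls, 100 sets of unchanged groups were simulated against shared controls. Alternatives were quantile normalization, no filter, a minimum of 5 FPKM, limma without trend, a pseudocount of 0.1, only the 2 groups compared, a replicate block, a fold minimum, and each library left out in turn. Median centring, removal of length and GC trends, and leaving out genes that share reads or genes of chromosomes 2 and 20 were added after the data were seen.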

Results

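Gene expression was measured by RNA sequencing in 9 libraries of human cells, titled as MDA-MB-231/PTX, a paclitaxel-resistant derivative of the triple-negative breast cancer line MDA-MB-231. By their titles, 3 libraries had a control siRNA (si-NC) and 3 had each of the siRNAs against the RNA BCLIN25 (si1-BCLIN25 and si2-BCLIN25). Other label fields name knockdown of HUMT instead, so the target is in dispute. The titles of the study place BCLIN25 in a relation with the microRNA miR-125b, chemotherapy resistance and the epithelial-mesenchymal transition, the loss of epithelial for mesenchymal traits. Between 11812 and 11856 genes reached 1 FPKM in the si-NC libraries and between 12091 and 12139 in the siRNA libraries. Depth is unknown, since the table holds FPKM. No label says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The control columns carry a prefix that the siRNA columns lack, so a difference in handling cannot be told apart from the groups.

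BCLIN25, the targeted RNA by the titles, was not analysed here, so the knockdown itself was not checked. RB1 (gene 5925), a brake on cell cycle entry named in the design text, was at 1.5 ± 0.069 FPKM in si-NC, 1.70 ± 0.29 in si1-BCLIN25 and 1.80 ± 0.15 in si2-BCLIN25 (SD, n = 3 each). Its limma test passed the threshold in neither siRNA group, with adjusted p = 0.293 and adjusted p = 0.112. RB1 lay close to the filter of 1 FPKM, where the log2(FPKM + 1) scale understates changes, so a change is not excluded. CREB1 (gene 1385), a cAMP-responsive transcription factor, rose from 12.2 ± 0.081 FPKM to 14.8 ± 0.58 and 15.5 ± 0.65, by 0.26 and 0.33 on the log2 scale (SE 0.045, limma adjusted p = 0.00024 and 4.4e-05). CREB1 lies on chromosome 2 in a window of 50 neighbouring tested genes, ORC2 to ATIC, whose median was also above si-NC, at 0.12 and 0.24.

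All 9 libraries expressed epithelial genes. The adhesion protein CDH1 lay between 31.4 and 46.5 FPKM, EPCAM between 92.7 and 143 FPKM and the splicing factor ESRP1 between 51.2 and 76.1 FPKM, while ZEB1, a repressor of epithelial genes, stayed at or below 0.14 FPKM. Of 20 genes listed in advance as high in MDA-MB-231, ZEB1 among them, 19 reached 1 FPKM in each si-NC library and 18 in each siRNA library. Most rows did so, at least 11812 of 18064 in each library. The median of the listed genes lay between 75.5 and 79.1 FPKM in si-NC and between 31.1 and 34.9 FPKM in the siRNA libraries. Of 21 genes listed as high in PC9, 15 reached 1 FPKM in each si-NC library and 17 in each siRNA library. Their median lay between 7.41 and 7.75 FPKM in si-NC and between 22.6 and 25.2 FPKM in the siRNA libraries. This shift overstates the change, since the middle gene was ESRP2 in si-NC and CLDN4, which fell, in si1-BCLIN25. Of 17 members tested, 12 rose and 4 fell in each siRNA group, with median log2 fold changes of 0.38 and 0.36. The list was not called (camera adjusted p = 0.170 and 0.125). But the lung genes NKX2-1 and NAPSA stayed at or below 0.78 and 0.34 FPKM. Stromal and blood cell markers ranged widely. The collagens COL1A2 and COL3A1 were at or below 0.04 FPKM, but the fibroblast marker THY1 lay between 10.6 and 15.8 FPKM and the leukocyte marker LAPTM5 between 36.3 and 58.0 FPKM. Of 5 fibroblast markers tested, 4 rose and 0 fell in each siRNA group, also adjusted over the list alone, with LUM from 0.50 to 4.97 and 4.01 FPKM and COL1A1 from 3.75 to 9.32 and 8.67 FPKM, and the list was not called (camera adjusted p = 0.0704 and 0.0855). The tumour suppressor CDKN2A, looked at after its values were seen, lay between 158 and 193 FPKM. The labels conflict on the cell line and on the targeted RNA, so groups are given below as titled.

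**Figure D1:**
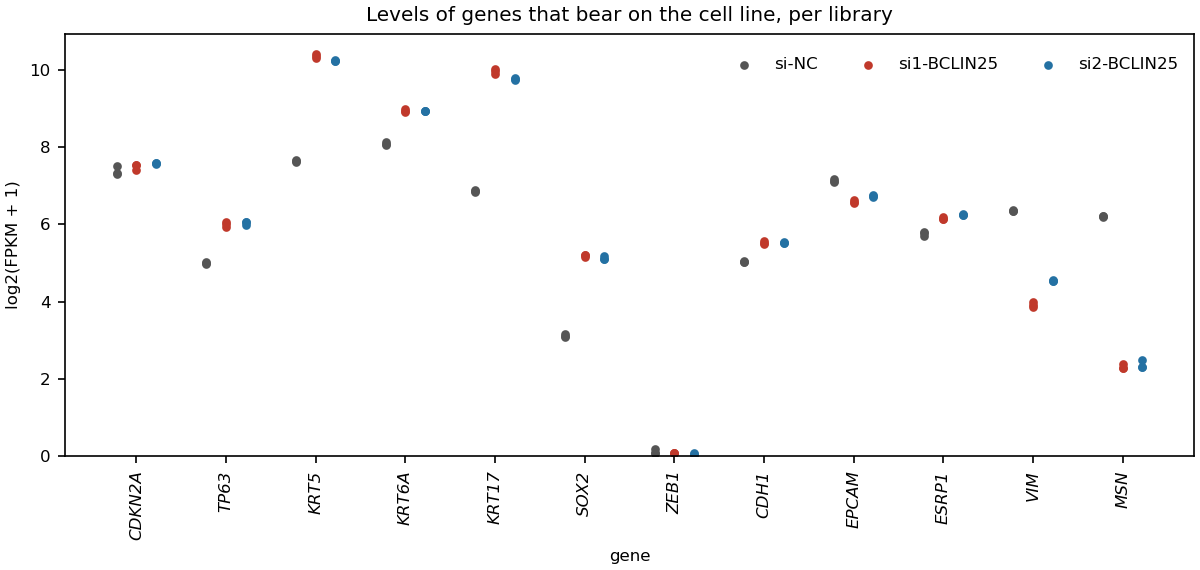
Levels of 12 genes that bear on the identity of the cells, as log2(FPKM + 1) on the y axis, with 1 point per library and 3 libraries per group. ZEB1 is near 0 and CDKN2A is high in all 9 libraries, and VIM and MSN are lower in both siRNA groups than in si-NC.

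The comparison of each siRNA group with si-NC asks which transcripts differ after treatment with an siRNA titled as against BCLIN25. The interstitial collagenase MMP1 (gene 4312) dropped from 570 ± 4.5 FPKM in si-NC to 5.99 ± 0.31 in si1-BCLIN25 and 5.42 ± 0.24 in si2-BCLIN25 (SD, n = 3 each). The log2 fold changes were -6.35 and -6.48 (SE 0.043), with limma adjusted p = 6.2e-17 and 5.0e-17. The stromelysin MMP10 (gene 4319) fell from 135 to 5.20 and 4.47 FPKM, and thrombospondin 1 (THBS1, gene 7057) from 438 to 51.0 and 56.1 FPKM. SERPINB2, an inhibitor of plasminogen activators, fell from 213 to 23.1 and 24.9 FPKM, and the cross-linking enzyme TGM2 from 338 to 45.0 and 46.5 FPKM. Cyclin D1 (CCND1), which drives entry into the cell cycle, fell from 109 to 14.3 and 14.8 FPKM. PTGS2, the inducible cyclooxygenase, fell from 109 to 15.1 and 15.9 FPKM, the ectonucleotidase NT5E from 113 to 14.9 and 17.3 FPKM and the EGFR ligand TGFA from 91.6 to 14.6 and 16.9 FPKM. EMP1, the transporter SLCO4A1 and the WNT antagonist DKK1 completed the 12 falls named for both groups. TGM2 and SLCO4A1 on chromosome 20 and TGFA on chromosome 2 lie on chromosomes where neighbouring genes were lower together, as described further on.

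A calcium-binding protein, a growth factor binding protein and a keratin were among the steepest rises. The calcium-binding protein S100A8 (gene 6279) rose from 7.33 ± 1.1 FPKM to 197 ± 5.8 and 139 ± 3.6, with log2 fold changes of 4.58 and 4.08 (SE 0.074, limma adjusted p = 1.3e-13 and 4.2e-13). The insulin-like growth factor binding protein IGFBP3 (gene 3486) rose from 27.2 to 428 and 385 FPKM. The basal keratin KRT17 (gene 3872) rose from 116 to 1001 and 867 FPKM, and the serpin SERPINB3 from 2.30 to 46.9 and 40.9 FPKM. TNFSF10, the death ligand TRAIL, rose from 2.67 to 43.0 and 37.0 FPKM, and the cytokine receptor chain IL20RB from 2.69 to 37.8 and 37.9 FPKM. The kallikrein KLK10, the retinoic acid binding protein CRABP2, the urea cycle enzyme ASS1 and MPPED2 also rose, ASS1 from 23.4 to 178 and 153 FPKM. SPANXC and SPANXA1, cancer-testis genes, rose from 1.44 to 53.3 and 46.5 FPKM and from 7.79 to 163 and 159 FPKM, with values that are uncertain because near-identical family members share reads. These genes supplied all 10 rises and all 10 falls named for each siRNA group alone.

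**Figure D2:**
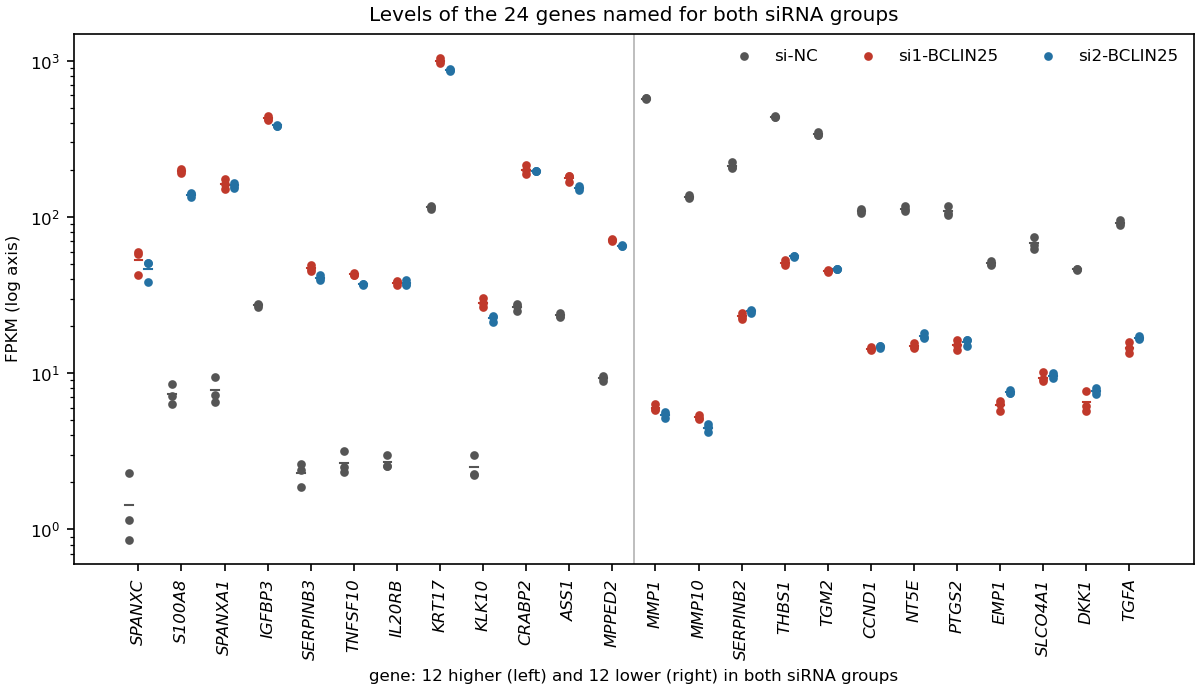
FPKM (log axis) of the 12 genes with the largest mean rise and the 12 with the largest mean fall in both siRNA groups. Each point is 1 library, each short line the mean of 3, and for every gene shown the 6 siRNA libraries lie on one side of the 3 si-NC libraries.

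Most of the transcriptome differed from si-NC. In si1-BCLIN25, 7766 of 12317 genes were called, 4731 higher and 3035 lower, and in si2-BCLIN25 7759 were called, 4756 higher and 3003 lower. Changes of at least 2-fold were fewer, 572 in si1-BCLIN25 (339 higher, 233 lower) and 560 in si2-BCLIN25 (344 higher, 216 lower). The median fold change over all genes was 0.06 in both on the log2 scale. Quantile normalization evened the split to 3797 higher and 3775 lower in si1-BCLIN25 and to 3814 higher and 3707 lower in si2-BCLIN25. The groups did not overlap for 64.7% and 67.1% of genes, where chance gives 10%.

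The siRNA groups changed alike. Called in both in the same direction were 6729 genes, 4157 higher and 2572 lower, and 1 gene was called in opposite directions. Independent lists of these sizes would share 1827 higher and 740 lower genes, and simulated unchanged groups against shared controls shared 0.05 genes on average and 2 at most. Across genes, which are not independent replicates, the fold changes correlated with r = 0.977 and rho = 0.950, against r = 0.501 in the simulation. Their covariance was 0.228 against 0.0025 simulated, and 89.9% had the same sign against 66.7%. The simulation holds only the random spread of the shared controls, not an offset common to them from cells or handling. With 3 controls the controls could not be divided so that each part kept at least 2 libraries. Such an offset was therefore not tested and could give any part of the excess. The first principal component held 86.7% of the variance and separated si-NC from all 6 siRNA libraries.

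Genes of growth factor and MYC programs fell. Of 25 measured receptor tyrosine kinase and MAPK feedback genes, 18 fell and 5 rose in si1-BCLIN25, and 18 fell and 4 rose in si2-BCLIN25 (18 and 5, and 18 and 5, adjusted over the list alone). Among them the MAPK phosphatase DUSP6 fell from 40.8 to 10.8 and 10.7 FPKM, DUSP4 from 73.2 to 17.7 and 19.5 FPKM and the transcription factor ETV4 from 31.0 to 6.86 and 7.69 FPKM. The camera adjusted p was 2.7e-08 and 1.5e-07. Of 29 measured MYC targets, most of them ribosome biogenesis genes, 25 fell and 0 rose in si1-BCLIN25 (25 and 0 adjusted over the list alone). In si2-BCLIN25 24 fell and 1 rose (26 and 1 adjusted over the list alone), with camera adjusted p = 2.7e-08 and 2.8e-08. UTP20 fell from 10.6 to 6.03 and 6.02 FPKM and the dyskerin gene DKC1 from 109 to 71.6 and 70.9 FPKM. WDR43 and POLR1B, which also fell, lie on chromosome 2, and without the genes of chromosomes 2 and 20 the list stayed called (2.4e-06 and 6.5e-07). The MDA-MB-231 list fell too, with 16 of 19 measured members lower and 3 higher in each siRNA group, over all genes and adjusted over the list alone (camera adjusted p = 2.6e-08 and 2.8e-08). The membrane linker moesin (MSN) dropped from 72.9 ± 1.2 FPKM to 3.98 ± 0.21 and 4.15 ± 0.36, and the AP-1 factor FOSL1 from 186 to 31.5 and 37.6 FPKM. LGALS1 went the other way, from 33.6 to 148 and 164 FPKM. The lists share members, so their calls are not independent. AXL, on this list, was the median gene of both this and the receptor tyrosine kinase list in si1-BCLIN25 (-0.91). VIM, also on this list, is counted again among the mesenchymal genes.

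Inflammatory, TGF-beta and mesenchymal lists also fell. Of 29 NF-kB and inflammatory genes, 16 fell and 7 rose in si1-BCLIN25, and 18 fell and 8 rose in si2-BCLIN25 (16 and 7, and 19 and 8, adjusted over the list alone), with camera adjusted p = 0.0049 and 0.0007. The cytokine LIF fell from 44.9 to 10.3 and 9.69 FPKM, while TNFAIP2 rose from 29.2 to 82.5 and 76.3 FPKM and SOD2, a mitochondrial antioxidant enzyme, from 55.7 to 113 and 106 FPKM. Of 24 TGF-beta response genes, 17 fell in each group, and 6 and 7 rose (the same counts adjusted over the list alone), among the falls the receptor TGFBR2, from 25.5 to 8.69 and 9.34 FPKM. The camera adjusted p was 1.0e-04 and 4.7e-05, but adjusted p = 0.1 and 0.0956 with an estimated correlation. Of 19 mesenchymal genes, 11 fell in each group, and 4 and 6 rose (the same counts adjusted over the list alone). Vimentin (VIM, gene 7431) fell from 80.9 ± 0.41 FPKM to 14.2 ± 0.70 and 22.4 ± 0.12, fibronectin (FN1) from 514 to 126 and 139 FPKM and N-cadherin (CDH2) from 67.1 to 23.6 and 21.9 FPKM, whereas CDH11 rose from 1.39 to 15.0 and 14 FPKM. FN1 lies on chromosome 2, beyond the low stretch described further on, in a window with medians of 0.20 and 0.12. The mesenchymal list had camera adjusted p = 0.003 and 0.0081, but adjusted p = 0.330 and 0.362 with an estimated correlation. The epithelial list was not called (camera adjusted p = 0.613 and 0.558), with 11 members higher and 6 lower in si1-BCLIN25 and 13 higher and 8 lower in si2-BCLIN25 (the same counts adjusted over the list alone). ELF3 rose from 5.51 to 37.0 and 37.4 FPKM and KRT19 from 688 to 1665 and 1555 FPKM, while KRT18 fell from 299.8 to 175 and 178 FPKM.

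Interferon-stimulated genes and targets of NRF2, the regulator of the oxidative stress response, rose. Of 31 interferon-stimulated genes, 24 rose in si1-BCLIN25 and 27 in si2-BCLIN25, and 0 fell (25 and 27 rose adjusted over the list alone), with camera adjusted p = 5.9e-06 and 2.3e-06. The antiviral GTPase MX1 rose from 1.87 to 6.41 and 6.28 FPKM and SAMD9 from 12 to 28.3 and 27.8 FPKM. Of 23 NRF2 targets, 19 rose and 2 fell in each group (19 and 3, and 19 and 2, adjusted over the list alone), with camera adjusted p = 3.6e-05 and 4.7e-05. The aldo-keto reductase AKR1C3 rose from 7.06 to 31.1 and 27.2 FPKM, and NQO1 from 24.5 to 41.9 and 41.5 FPKM.

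Cholesterol biosynthesis and stress response lists also rose. Of 25 cholesterol biosynthesis genes, 21 rose and 2 fell in si1-BCLIN25 and 16 rose and 3 fell in si2-BCLIN25 (22 and 2, and 16 and 3, adjusted over the list alone), with camera adjusted p = 0.00035 and 0.0498. FDFT1, the squalene synthase, rose from 94.0 to 179 and 154 FPKM. With an estimated correlation the si2-BCLIN25 call was lost (adjusted p = 0.126). It was also lost when si-NC replicate 2 or 3, si1-BCLIN25 replicate 2 or 3, or si2-BCLIN25 replicate 1 was left out, with adjusted p = 0.0524, 0.0656, 0.0582, 0.0541 and 0.0566 in that order, within a range of 0.0127 to 0.126 over the alternatives of the camera test. A minimum of 5 FPKM (0.051) and leaving out chromosomes 2 and 20 (0.0723) ended it too. Of 26 genes of the unfolded protein and integrated stress responses, 19 and 18 rose and 5 and 4 fell (the same counts adjusted over the list alone), with camera adjusted p = 0.0272 and 0.0211, but adjusted p = 0.106 and 0.0956 with an estimated correlation. The serine synthesis enzyme PHGDH rose from 72.9 to 138 and 136 FPKM, and PPP1R15A, which restores translation after stress, fell from 56.2 to 25.9 and 27.5 FPKM. Oxidative phosphorylation and ribosomal protein genes passed the threshold in si1-BCLIN25 (camera adjusted p = 0.0272 and 0.036) and not in si2-BCLIN25 (0.224 and 0.168). Of 30 and 40 measured members, 20 and 26 rose in si1-BCLIN25 (20 and 27 adjusted over the list alone), by medians of 0.16 each (0.17 for oxidative phosphorylation and 0.058 for ribosomal proteins under quantile normalization), and with an estimated correlation both calls were lost (adjusted p = 0.538 and 0.727). The ribosomal call was also lost when si-NC replicate 3 (0.0984) or si1-BCLIN25 replicate 2 (0.0628) or 3 (0.0746) was left out, and the oxidative phosphorylation call without si1-BCLIN25 replicate 3 (0.0776). Removing length and GC trends ended the ribosomal call (0.118). Over the alternatives of the camera test the adjusted p ranged from 0.0084 to 0.727 for ribosomal proteins and from 0.0074 to 0.538 for oxidative phosphorylation.

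**Figure D3:**
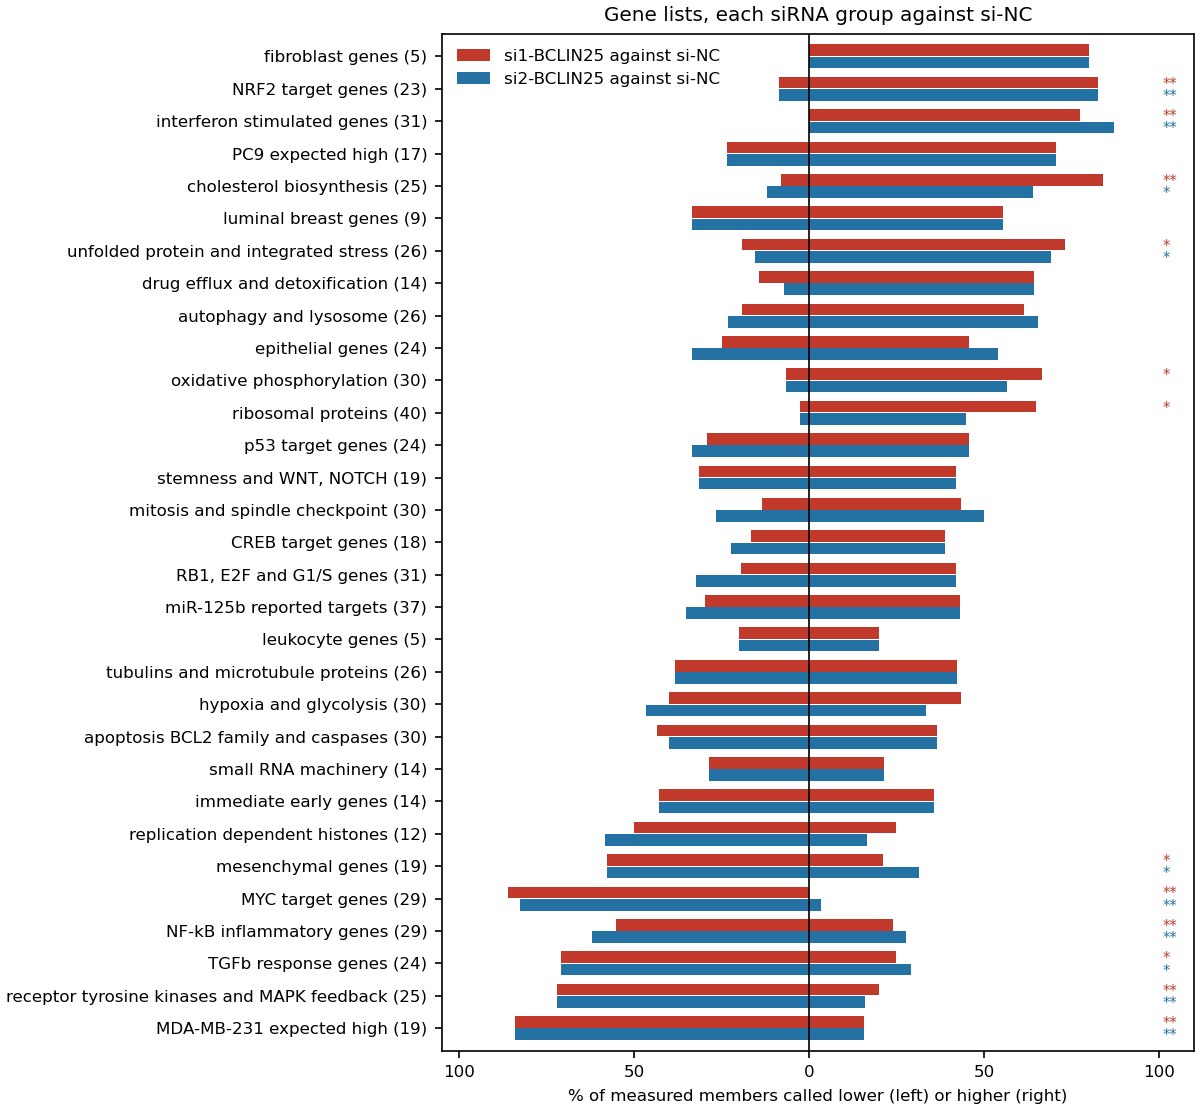
Share of measured members (number in parentheses) of each of 31 lists called lower (left) or higher (right) against si-NC, in si1-BCLIN25 (red) and si2-BCLIN25 (blue). A star marks lists called by camera with the preset correlation and 2 stars those also called with an estimated correlation, 7 lists in si1-BCLIN25 and 6 in si2-BCLIN25.

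Lists tied to the stated subject of the study held rises and falls side by side. Of 37 reported miR-125b targets, 16 rose and 11 fell in si1-BCLIN25 and 16 rose and 13 fell in si2-BCLIN25 (17 and 11, and 16 and 13, adjusted over the list alone), with camera adjusted p = 0.812 and 0.719. Its median (0.031 and 0.0052) and mean were above 0 and its camera direction was down. The median turned negative under median centring in both groups and under quantile normalization in si2-BCLIN25. The sialomucin PODXL fell from 77.4 to 20.6 and 19.9 FPKM and ETS1 from 47.1 to 16.8 and 20.1 FPKM, whereas the pro-apoptotic BMF rose from 3.27 to 14 and 12.3 FPKM. Of 26 tubulin and microtubule genes, the targets and partners of paclitaxel, 11 rose and 10 fell in each group (the same counts adjusted over the list alone), with camera adjusted p = 0.666 and 0.558. In si1-BCLIN25 the median of this list was above 0 and its mean and camera direction below, and the median turned negative with other scaling. STMN3 fell from 29.6 to 6.87 and 7.15 FPKM and TUBA1A rose from 38.1 to 62.2 and 62.7 FPKM. Of 14 drug efflux and detoxification genes, 9 rose in each group and 2 and 1 fell (the same counts adjusted over the list alone), but the list was not called (camera adjusted p = 0.120 and 0.0855). CYP1A1 rose from 4.85 to 20.7 and 23.1 FPKM and CYP1B1 fell from 8.97 to 0.40 and 0.39 FPKM. STMN3 lies on chromosome 20 and CYP1B1 in the low stretch of chromosome 2 described further on. Without the genes of these chromosomes the efflux list was called (camera adjusted p = 0.0369 and 0.0212, within ranges over the alternatives of the camera test of 0.0369 to 0.423 and 0.0212 to 0.296).

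Cell death and cell cycle lists were not called. Of 30 apoptosis genes, 11 rose and 13 fell in si1-BCLIN25 and 11 rose and 12 fell in si2-BCLIN25 (11 and 14, and 11 and 12, adjusted over the list alone), with camera adjusted p = 0.274 and 0.302. Of 24 p53 targets, 11 rose in each group and 7 and 8 fell (11 and 7, and 12 and 8, adjusted over the list alone), with camera adjusted p = 0.884 and 0.844, a median above 0 and a camera direction below. Of 30 mitotic genes, 13 and 15 rose and 4 and 8 fell (the same counts adjusted over the list alone), with camera adjusted p = 0.489 and 0.837. Of 31 E2F and G1/S genes, 13 rose in each group and 6 and 10 fell (13 and 6, and 14 and 10, adjusted over the list alone), with camera adjusted p = 0.613 and 0.987, and in si2-BCLIN25 the median was above 0 with a camera direction below. Within them, the anti-apoptotic BCL2L1 (on chromosome 20) fell from 124 to 46.5 and 44.9 FPKM and the mitotic kinesin KIF20A rose from 19.6 to 31.8 and 29.3 FPKM.

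Neighbouring genes differed together between si-NC and both siRNA groups. In 233 windows of 50 neighbouring tested genes, the variance of the median fold change was 5.26 times its mean over 1000 shuffled gene orders in si1-BCLIN25 and 4.84 times in si2-BCLIN25. Windows with a median under -0.1 in both siRNA groups were taken as low. The longest stretch of low windows took up 11 windows on chromosome 2, from FAM110C to METTL5. There 435 of 550 genes lay below si-NC in si1-BCLIN25 and 426 of 550 in si2-BCLIN25. Its window medians ran from -0.45 to -0.11 and from -0.43 to -0.12 on the log2 scale, and those of the next window were 0.02 and 0.13. Windows on chromosome 20 were low as well, and the lowest of them differed between the siRNA groups. It was at -0.31 from TRMT6 to PYGB in si1-BCLIN25 and at -0.33 from TSHZ2 to GMEB2 in si2-BCLIN25. Other windows were high by about as much. The medians were 0.31 and 0.24 from LIG1 to RRAS on chromosome 19 and 0.29 and 0.29 from PHACTR4 to RNF19B on chromosome 1. From VARS2 to RXRB on chromosome 6 they were 0.28 and 0.22. The neighbouring window on chromosome 1, from SYF2 to MED18, was at 0.23 in both siRNA groups. Runs of high windows were not searched for. Medians of adjacent windows correlated with r = 0.70 in both comparisons with si-NC and 0.42 between the siRNA groups. With length and GC trends removed, r was 0.72 for si1-BCLIN25, 0.71 for si2-BCLIN25 and 0.14 between them. In a separate, smaller set of shuffled gene orders window medians ran from -0.19 to 0.30 in si1-BCLIN25 and from -0.16 to 0.34 in si2-BCLIN25. The chromosome 20 medians given lay beyond these ranges, but of the high ones only 0.31 in si1-BCLIN25 did. The ranges are extremes over all windows and orders, so a median within them can still be unusual for a single window. Between the siRNA groups no window median went beyond -0.09 and 0.07. Their variance was still 4.29 times its mean over shuffled gene orders. After length and GC trends were removed it was 1.5 times, against 4.88 and 4.81 times for the comparisons with si-NC. Without the genes of chromosomes 2 and 20, 5939 genes were called in both siRNA groups in the same direction.

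**Figure D4:**
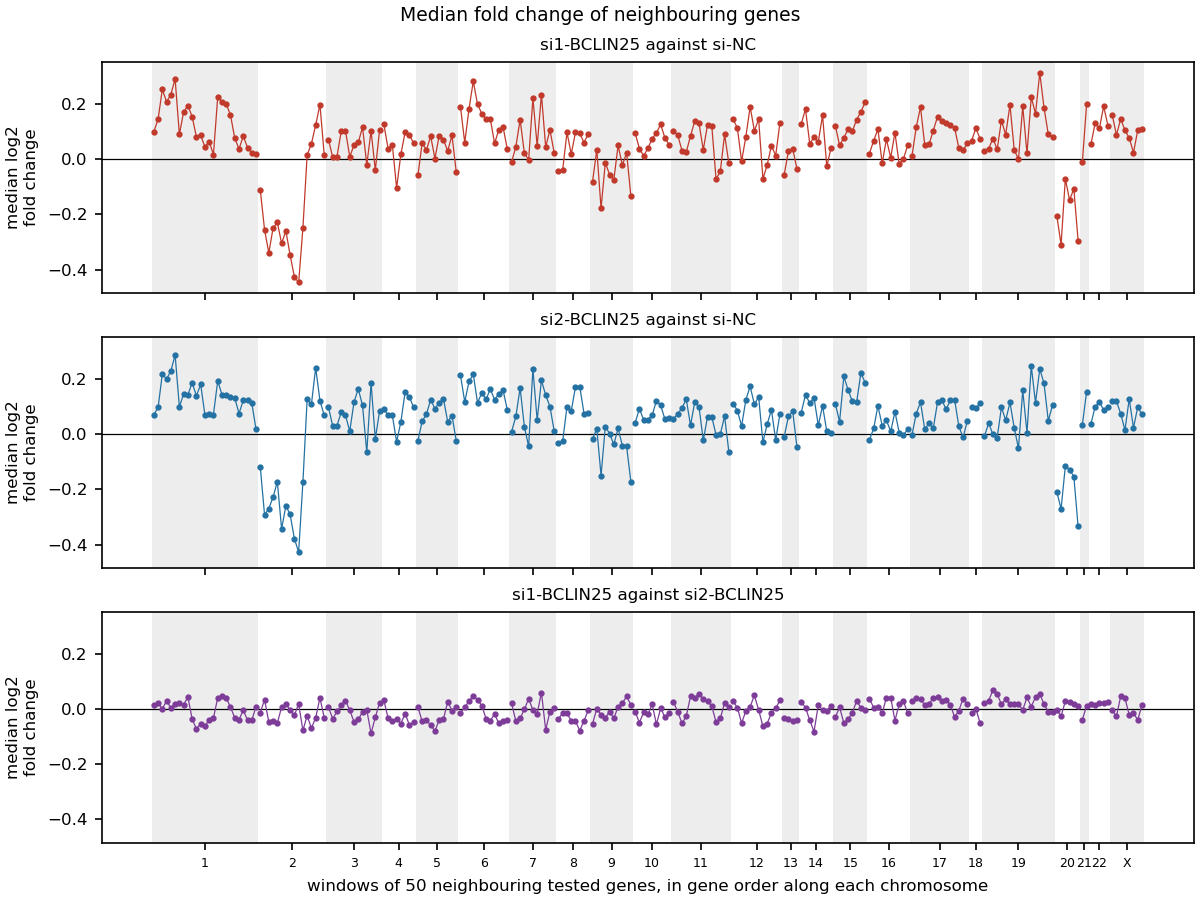
Median log2 fold change (y axis) of 233 windows of 50 neighbouring tested genes in order along chromosomes 1 to 22 and X (x axis, shaded in turn), for the 3 comparisons. Both comparisons with si-NC show a low stretch over most of chromosome 2 and over chromosome 20, and the comparison of the siRNA groups stays between -0.09 and 0.07.

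Comparing si1-BCLIN25 with si2-BCLIN25 asks where the siRNAs differ from each other. A protease inhibitor and vimentin differed most among the genes named. The protease inhibitor PI3 (gene 5266) was at 17.8 ± 0.39 FPKM in si1-BCLIN25 and 9.38 ± 0.53 in si2-BCLIN25 (SD, n = 3 each), a log2 difference of 0.86 (SE 0.097, limma adjusted p = 0.0078), beside 16.4 ± 3.0 in si-NC. The cornified envelope protein SPRR1B (33.3 against 22.7 FPKM), S100A8 (197 against 139 FPKM), the growth factor carrier FGFBP1 (26.4 against 19.5 FPKM) and PQBP1 (43.3 against 34.3 FPKM) were also higher in si1-BCLIN25. VIM was lower, at 14.2 ± 0.70 against 22.4 ± 0.12 FPKM, a difference of -0.63 (SE 0.039, limma adjusted p = 2.2e-05). Galectin 3 (LGALS3, 22.6 against 29.8 FPKM), KRT80 (27.6 against 35.8 FPKM), the antimicrobial RNASE7 (14.7 against 19.2 FPKM) and ARHGAP29 (8.35 against 10.5 FPKM) were lower too, with adjusted p between 0.0172 and 0.0338. PI3 and VIM were still called with each library left out in turn, but the PI3 call was lost without the filter on low values (adjusted p = 0.0541, the highest of a range from 5.3e-05 over its alternatives without a fold minimum). The other 8 calls were lost without si1-BCLIN25 replicate 3 and without si2-BCLIN25 replicate 3, and most also without si1-BCLIN25 replicate 2 or si2-BCLIN25 replicate 1 or 2, and PQBP1 without si1-BCLIN25 replicate 1, with adjusted p between 0.051 and 0.154. All 8 were also lost without the filter on low values, and SPRR1B, S100A8, FGFBP1, PQBP1 and LGALS3 in limma without trend, so that of the 10 genes VIM alone kept its call under every setting without a fold minimum. PI3 lies on chromosome 20. In all, 72 genes were called, 38 higher and 34 lower, 0 of them at least 2-fold in the limma test, and 2187 had an unadjusted p under 0.05. The count rested on single libraries. It was 5 without si1-BCLIN25 replicate 2 or 3, 3, 8 and 2 without si2-BCLIN25 replicates 1, 2 and 3, and 126 without si-NC replicate 1.

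Cholesterol biosynthesis genes stood apart between the siRNA groups. All but 2 of its 25 genes missed the threshold over all genes, and 15 were called higher in si1-BCLIN25 adjusted over the list alone, with camera adjusted p = 1.7e-10 and adjusted p = 0.0079 with an estimated correlation. DHCR7, the last enzyme of the pathway, was at 40.5 against 32.9 FPKM, and HSD17B7 at 16.2 against 13.9 FPKM. The call of DHCR7 was lost without si1-BCLIN25 replicate 2 or any si2-BCLIN25 library, and that of HSD17B7 without any of the 6 siRNA libraries left out in turn, while the list stayed called (camera adjusted p between 1.8e-12 and 0.0079 over its alternatives). Of the 8 lists called, the other calls were lost with an estimated correlation. NF-kB genes (camera adjusted p = 0.00094, but adjusted p = 0.0687 with an estimated correlation), replication-dependent histones (0.0024, but 0.3), E2F and G1/S genes (0.0024, but 0.3), oxidative phosphorylation (0.0024, but 0.57) and ribosomal proteins (0.0484, but 0.681) were higher in si1-BCLIN25. The MDA-MB-231 list (0.00033, but 0.0777) and the receptor tyrosine kinase and MAPK list (0.0207, but 0.367) were lower. Adjusted over the list alone, 7, 5, 1, 5 and 0 genes of the former and 6 and 5 of the latter were called in those directions, against 3, 1, 0, 0 and 0 and 4 and 1 over all genes. The oxidative phosphorylation call was lost without si1-BCLIN25 replicate 3 (adjusted p = 0.145), and the ribosomal call without si-NC replicate 2 (0.0638), si1-BCLIN25 replicate 2 (0.0732) or 3 (0.331) or si2-BCLIN25 replicate 2 (0.198). Without a filter (0.0663) or with a minimum of 5 FPKM (0.0789) the ribosomal call was lost too, and leaving out the genes of chromosomes 2 and 20 ended both the ribosomal and the receptor tyrosine kinase and MAPK calls (0.0641 each, within ranges over the alternatives of the camera test of 0.0065 to 0.681 and 0.0012 to 0.367). Transcript length and GC content explained 11.3% of the variance of these differences, against 0.72% for si1-BCLIN25 and 0.31% for si2-BCLIN25 compared with si-NC. With length and GC trends removed from each library, 132 genes and 12 lists were called between the siRNA groups, against 72 and 8, with the epithelial, mesenchymal, mitotic, immediate early and PC9 lists gained and the ribosomal call lost (adjusted p = 0.369).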

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

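The test of length and GC trends between the siRNA groups and the counts of other splits of the libraries were chosen after the results were seen. The change from si-NC differed between the siRNA groups for 72 genes in the limma test of the difference itself. As log2 fold change in si1-BCLIN25 minus that in si2-BCLIN25, the differences were 0.86 for PI3, 0.53 for SPRR1B, 0.51 for S100A8, 0.42 for FGFBP1 and 0.33 for PQBP1. They were -0.63 for VIM, -0.38 for LGALS3, -0.36 for KRT80, -0.36 for RNASE7 and -0.30 for ARHGAP29. VIM fell in both groups and fell further in si1-BCLIN25, whereas PI3 fell in si2-BCLIN25 alone by the test and was at a log2 fold change of 0.13 in si1-BCLIN25 (adjusted p = 0.267).

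A bias by transcript length or GC content could account for a difference between the siRNA groups, since both explained 11.3% of its variance. After removal of these trends 132 genes were called, against 72. This rise cannot weigh the bias, since the count also ran from 2 to 126 when 1 library was left out. Of the 72 genes, 60 were called in the same direction after the removal, so those calls did not rest on the trends removed. The window variance between the siRNA groups fell from 4.29 to 1.5 times that of shuffled gene orders. That regional part of the difference therefore went largely with length and GC content. An off-target effect of either siRNA, or unequal knockdown, stays open and was not tested, since BCLIN25 was not analysed here. The count was 5 without si1-BCLIN25 replicate 2 or 3, 3, 8 and 2 without si2-BCLIN25 replicates 1, 2 and 3, and 126 and 107 without si-NC replicates 1 and 2.

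With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Between the siRNA groups 1 of the 10 splits gave as many genes (72, highest other 0) and 1 of 10 as many lists (8, highest other 5). For si1-BCLIN25 against si-NC these were 1 of 10 for genes (7766, highest other 0) and 1 of 10 for lists (12, highest other 10). For si2-BCLIN25 they were 1 of 10 for genes (7759, highest other 0) and 2 of 10 for lists (10, highest other 11). For genes called in both siRNA groups, 1 of 100 splits of the 9 libraries gave as many (6729). The highest other split gave 6673, in 1 of the 2 splits that kept the 3 controls together, and the rest gave 0 at most. So the count turned on whether the 3 controls stayed together, and argues against chance for that division alone. The splits say little on how the siRNA libraries were divided. They cannot tell treatment from a difference in handling of the controls.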

How the results depend on the processing

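Median centring, removal of length and GC trends, and leaving out genes that share reads or genes of chromosomes 2 and 20 were chosen after seeing the data. Without the fold minimum, the planned and added settings gave between 6126 and 8335 genes for si1-BCLIN25 against si-NC, 6098 to 8385 for si2-BCLIN25 and 5286 to 7152 for both in the same direction. Leaving out 1 library gave 7257 to 7659, 7073 to 7741 and 6280 to 6548. The fold minimum of 2 left 572, 560 and 510 by its construction, and 0 between the siRNA groups. The median fold change over all genes was 0.06, and quantile normalization took the share of higher calls from 60.9% to 50.1% and from 61.3% to 50.7%. Of 7766 genes 6761 were still called in the same direction in si1-BCLIN25 and 1 in the other, and of 7759 genes 6665 and 0 in si2-BCLIN25. No named gene changed direction with a call.

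Between the siRNA groups the count of 72 moved to 3 without a filter and 110 with a minimum of 5 FPKM (18064 and 9474 genes tested), 13 without trend, 230 with only the 2 groups, and 132 with length and GC trends removed. Leaving out 1 library gave 2 to 126 (126, 107, 90 without si-NC replicates 1, 2, 3, then 67, 5, 5 for si1-BCLIN25 and 3, 8, 2 for si2-BCLIN25). The cause was not tested.

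With the replicate number as a block, 7665, 7626 and 6646 genes were called against si-NC and in both, and 6 between the siRNA groups, where S100A8, FGFBP1, PQBP1, LGALS3 and ARHGAP29 lost their calls. Lists numbered 11, 10 and 7, with the ribosomal calls lost (adjusted p = 0.0569 and 0.0786). The numbers did not pair the libraries, since deviations of same-numbered libraries correlated between -0.16 and 0.14 over 9 pairs.

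List counts of 12, 10 and 8 became 7, 6 and 1 with an estimated correlation and 24, 24 and 5 with fry, which does not compare a list with other genes. Fry called stemness genes in si1-BCLIN25 (adjusted p = 0.0019) and E2F and G1/S genes in si2-BCLIN25 (0.0061) higher, where camera gave the other direction without a call. Leaving out 1 library gave 10 to 13, 9 to 12 and 6 to 9 lists. Size factors and count models could not be run on FPKM, and without depth no limit of detection can be given.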

Other observations

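The test of the cell line as titled, the test for the targeted RNA and the lists of squamous and of YAP and TAZ target genes were chosen after the data were seen. The squamous and keratinocyte list was drawn up once KRT17, S100A8 and other members were known to have risen, so its counts describe these genes and test nothing. Of 30 measured, 28 rose and 1 fell in si1-BCLIN25 and 27 rose and 1 fell in si2-BCLIN25. The basal keratin KRT5 rose from 199 to 1318 and 1210 FPKM, KRT14 from 0.52 to 23.7 and 19.4 FPKM and S100A9 from 503 to 2456 and 1968 FPKM. The transcription factor TP63, which drives the basal epithelial program, rose from 31.1 to 63.4 and 64.4 FPKM, and SOX2 from 7.67 to 35.6 and 33.9 FPKM.

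The list of targets of YAP and TAZ, effectors of the Hippo pathway, was likewise drawn up after falls among them were seen. Of 20 measured, 14 fell in each group and 2 and 3 rose. ANKRD1 fell from 13.4 to 0.52 and 0.65 FPKM, CCN2 from 7.94 to 1.08 and 1.32 FPKM and the receptor kinase AXL from 97.0 to 51.3 and 58.9 FPKM. The immune checkpoint ligand CD274 fell from 14.8 to 2.79 and 3.88 FPKM and the cytokine IL1B from 336 to 155 and 160 FPKM, both named after their values were seen. Of the other lists fixed in advance, autophagy and lysosome genes (camera adjusted p = 0.303 and 0.224), hypoxia genes (0.613 and 0.302), stemness genes (0.919 and 0.98), CREB targets (0.72 and 0.841), small RNA machinery (0.613 and 0.338), immediate early genes (0.393 and 0.43) and histones (0.418 and 0.0855) were not called. Nor were the PC9 list (0.17 and 0.125), luminal (0.746 and 0.841), fibroblast (0.0704 and 0.0855) and leukocyte genes (0.613 and 0.74).

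The si-NC libraries stood far from both siRNA groups. Scaling is argued against by 6500 genes called in both groups under quantile normalization, against 6729, and length and GC content by the 0.72% of variance they explained in si1-BCLIN25. A candidate explanation is that the control and siRNA libraries came from cells of different genomes, and the windows cannot say which side departs. It rests on window medians, which varied 4.84 times as much as in shuffled gene orders. After length and GC trends were removed the ratio was 4.81, which argues against regional GC content. That ratio is not specific by itself, as it was 4.29 between the siRNA groups before that removal and 1.5 after it, and windows explained only 5.69% of the gene variance. Loss of BCLIN25 cannot be told apart from a difference in cells or handling, since its level could not be looked up and the control columns carry their own prefix. Loss of HUMT, the RNA that other label fields name, was not tested either. The gene names used here held 0 entries for BCLIN25. The 0 rows found under its name therefore do not show that it was absent from the deposited values.

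The cell line of all 9 libraries is a second open point. CDKN2A, known as deleted from the genome of MDA-MB-231, was at 158 FPKM in the library with the lowest value, which argues against MDA-MB-231 cells as titled. ZEB1, listed in advance as high in that line, stayed at or below 0.14 FPKM in all 9 libraries. Against this, 19 of the 20 genes on that list reached 1 FPKM in each si-NC library and 18 in each siRNA library. CDH1, EPCAM and ESRP1, from the PC9 list, were at least at 31.4, 92.7 and 51.2 FPKM. The basal genes TP63 and KRT5 were at least at 30.7 and 196 FPKM, also in si-NC. A mislabelled or different line may be involved, and which line it was could not be settled, since NKX2-1 and NAPSA, lung genes on the PC9 list, were at or below 0.78 and 0.34 FPKM.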
